A study of Arabidopsis thaliana with 12 samples.

How the data were processed

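Seedlings of 4 Arabidopsis thaliana genotypes were grown for 14 days on agar medium under long days and total RNA was sequenced as paired-end reads after a TruSeq library preparation, per the labels' protocols. The labels give 3 biological replicates for each genotype and also speak of RNA from biological replicates being pooled, so p-values may measure only the spread between these samples, which may be technical. The deposited table holds counts of reads per locus, which the authors made from alignments with TopHat2 to TAIR10, per the submitters' processing notes. The version of the aligner, the counting tool, its strand setting and any removal of duplicate reads are not given in the sources used here.

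The counts as deposited cover 29420 loci of the nuclear chromosomes, of which 28932 matched a locus of the TAIR10.1 annotation by identifier and 488 did not, and 3472 held 0 in all libraries. No organelle locus is in the table. Totals ran from 10119148 to 11860892 counts per library. No locus exceeded 6707 counts, the 10 highest loci took 0.41 to 0.46% of a library, and the gene of a Rubisco small subunit, RBCS1A, averaged 1237 counts, so differences among the most abundant transcripts may be compressed in these counts. The value 2 occurred 7320 times and the value 1 4554 times, an excess that counting both mates of a read pair may give. Of the values from 1 to 20, 56.4% were even, so not all counts come in pairs. Where both mates were counted, intervals based on single counts are too narrow. Intervals and floors cover counting error only. Intervals for BRM and for pooled loci take 2 counts as 1 fragment. Genes that overlap, antisense pairs and near-identical copies (LHCB1, RBCS, SAUR19 to SAUR24, CBF, PDF1, MAF and SESA genes) are uncertain, because the counting could split or share their reads.

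Counts of the 12 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, one mean per genotype and no further covariate, with TMM normalization (a trimmed mean of ratios) and the filterByExpr filter, which kept 22076 genes. Differences were tested with the robust quasi-likelihood F test, two-sided, and adjusted after Benjamini-Hochberg over the genes tested. A gene passed at an adjusted p under 0.05 with no fold minimum. Standard errors of log2 changes were taken from the F statistic. CPM values are counts scaled to the normalized library size, given as mean ± SD over 3 libraries. Where a group had 0 counts in all libraries, the fold was bounded with a floor of 3 counts over the group, and with 1 to 3 counts over the group the ratio is given with a 95% exact binomial interval. The interaction contrast was (brm-1 ref6-1 minus brm-1) minus (ref6-1 minus WT).

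Before the data were examined, 20 gene lists with 309 members were fixed by locus identifier, and 3 members (UGT75C1, JMJ13 and SWI3D) were left out because symbol and locus did not match. They cover flowering time, floral organ identity, seed maturation, meristem and organ boundary, auxin, brassinosteroid, gibberellin, cytokinin, abscisic acid and cold, salicylate defence, jasmonate and ethylene defence, glucosinolates, flavonoids, photosynthesis, the circadian clock, root markers, expansins and xyloglucan enzymes, the cell cycle, Polycomb and H3K27 demethylases, and SWI/SNF subunits. Lists with at least 5 measured members were tested with camera of limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation. BRM and REF6 were left out of their lists in these tests. Also fixed beforehand was the rule for named genes. It takes BRM, REF6 and 11 regulators of development (1 of which is not reported here), the largest rises and falls among genes with a symbol, a mean of at least 2 CPM and no overlap of the libraries, the best 2 members of each list against WT (1 in other comparisons), and the largest changes shared by both single mutants. All genes with the largest rises and falls are named. List members by the rule are given for lists that passed the set test and, in the combined mutant against WT, as the first member of every list, and in comparisons between mutants the first 8 in order of adjusted p are named and the rest counted. Other list members, AT5G24240 and AT1G14250 were named after their values were seen. Where the loss of a call is stated, the range of adjusted p beside it runs over all alternatives computed for that result, other tools included.

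Overlap of the single mutants was set beside that of independent lists and of 10 simulations of unchanged groups against the shared WT libraries. Alternatives were DESeq2 1.42.0, its size factors within edgeR, limma-voom, no filter on low counts, at least 1 CPM in 6 libraries, only the groups compared, a 2-fold minimum, an adjusted p under 0.01, the replicate number as a block, and each library left out. For folds against a group with at most 3 counts, leaving out libraries of the other group was chosen after the data were seen, as were the camera tests of single lists and the list medians without each library. On simulated counts for brm-1 against WT (21805 genes), the test called 71 of 100 genes changed 1.5-fold and 86 of 100 changed 2-fold, and 7 of 21590 unchanged genes. Replicate pairs gave a chi-square over degrees of freedom of 1.63 to 4.2, where sampling alone gives about 2 if both mates were counted. The lowest, of brm-1 ref6-1 replicates 2 and 3, is within sampling noise on that reading, but with 2 counts per fragment 104 loci differed beyond a limit that 21.5 would pass by sampling, and the libraries held 35 and 438 BRM counts, so each was kept as a library of its own. Figures were drawn with matplotlib.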

Results

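RNA was sequenced from 14-day-old Arabidopsis thaliana seedlings of 4 genotypes: wild type (WT), the mutants brm-1 and ref6-1, and the combined mutant brm-1 ref6-1. BRM encodes the ATPase of a SWI/SNF chromatin-remodelling complex. REF6 encodes a demethylase that removes the methylation placed by Polycomb proteins on lysine 27 of histone H3. Each genotype had 3 libraries, 12 in all, with 10119148 to 11860892 counts over 29420 loci, and 22076 genes passed the filter on low counts. On the first principal component of the log2 CPM values (41.4% of the variance), WT libraries lay between -46.9 and -40.5, single-mutant libraries between -16.6 and 18.5, and combined-mutant libraries between 26.3 and 56.1. On the second (23.6%), brm-1 lay between 29.8 and 37.4 and ref6-1 between -40.5 and -24.8.

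The BRM transcript (AT2G46020, chromosome 2, 18922533 to 18932055, TAIR10.1 annotation) was counted 3282, 2998 and 3067 times in WT replicates 1, 2 and 3, and 43, 50 and 74 times in brm-1. In ref6-1 it was counted 3012, 2761 and 3003 times. The combined mutant held 60 and 35 counts in replicates 1 and 2 but 438 in replicate 3, which is 14.7% of the WT level (95% exact Poisson interval 12.8 to 16.7%, counting error only). BRM fell by 5.77 ± 0.56 on the log2 scale in brm-1 (SE, n = 3 per group, edgeR adjusted p = 0.000214). It fell by 4.03 ± 0.46 in the combined mutant (edgeR adjusted p = 0.000311), a value of -5.90 without replicate 3. REF6 (AT3G48430, chromosome 3, 17935256 to 17940792) had 89.5 ± 6.65 CPM in WT, 90.4 ± 0.894 in brm-1, 80.5 ± 2.59 in ref6-1 and 79.4 ± 0.711 in the combined mutant (SD, n = 3). Its log2 difference in ref6-1, -0.15 ± 0.05, missed the threshold (edgeR adjusted p = 0.06, 0.00606 to 0.225 over the alternatives) and passed it at -0.21 without WT replicate 3. In the combined mutant REF6 fell by 0.17 ± 0.05 (edgeR adjusted p = 0.0135), a call that ended without WT replicate 1 (0.059, 0.00108 to 0.059 over the alternatives). A mutant allele can still be transcribed, so these REF6 counts do not check the ref6-1 label.

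**Figure D1:**
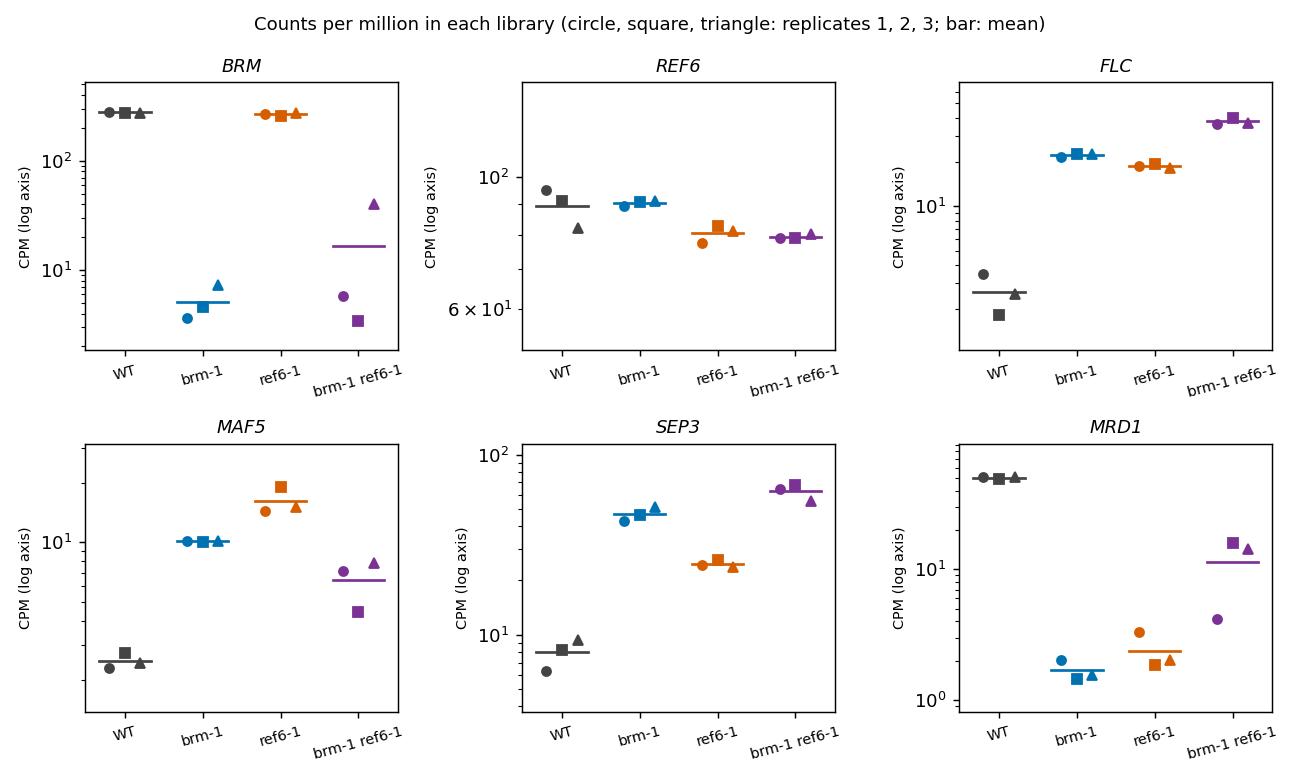
CPM (counts scaled to library size, log axis, scaled separately in each panel) of 6 genes in the 12 libraries, by genotype, where markers give replicates 1, 2 and 3 and bars the mean of 3. BRM was counted 438 times in replicate 3 of brm-1 ref6-1 against 60 and 35 in replicates 1 and 2, and FLC lay above all WT libraries in every mutant library.

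The first comparison asks which transcripts depend on BRM. In brm-1, FLC (AT5G10140, chromosome 5, 3173382 to 3179448), a MADS-box repressor of flowering, rose from 2.62 ± 0.832 CPM in WT to 22.4 ± 0.609 CPM (SD, n = 3). This is a log2 change of 3.08 ± 0.14 (SE, edgeR adjusted p = 1.52e-07). FT and CO, which promote flowering, rose by 1.29 ± 0.16 and 1.19 ± 0.12, and the floral gene SEP3 rose by 2.55 ± 0.12 (edgeR adjusted p = 3.31e-07). SOC1 rose by 0.25 ± 0.06, while the flowering regulators AGL24 and SVP changed by -1.74 ± 0.17 and -0.19 ± 0.04.

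The largest rises in brm-1 began with FOP1, which had 152 counts over the 3 brm-1 libraries against 2 in WT, both in the same library. This is a ratio of 77.5 (95% exact interval 21.1 to 646, counting error only). The seed storage globulin gene CRA1 (5.93 ± 1.16), the late embryogenesis gene M17 (3.68 ± 0.60), the defensin-like LCR67 (3.35 ± 0.52), the lipid transfer gene LTP4 (3.22 ± 0.47) and FLC came next. Largest among the falls were CYP71A20 (-6.18 ± 0.56), BRM, MRD1 (-4.88 ± 0.42), ARD3 (-4.05 ± 0.41), ELF4-L1 (-3.37 ± 0.41) and AIR1 (-3.33 ± 0.26). REF6 differed by 0.01 ± 0.05 and did not pass. CRA1 was counted 70, 176 and 18 times in the 3 brm-1 libraries, and its call (edgeR adjusted p = 0.00577) ended with limma-voom (0.115, 2.88e-06 to 0.115 over the alternatives). Its log2 change was 4.92 without brm-1 replicate 2, and that of M17 was 4.53 without WT replicate 2. SOC1 was no longer called without WT replicate 1 (edgeR adjusted p = 0.0609), brm-1 replicate 2 (0.0612) or brm-1 replicate 3 (0.0525), with 0.00847 to 0.0612 over the alternatives.

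Among 26 measured flowering time regulators, 9 rose and 3 fell in brm-1 (12 and 5 adjusted over the list alone). The list lay higher than other genes (camera adjusted p = 6.12e-05, and adjusted p = 0.0196 with an estimated correlation). Of 9 floral organ identity genes, SEP3 and AG (1.2 ± 0.28) rose and CAL fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.000164, and adjusted p = 0.0256 with an estimated correlation). Seed maturation genes rose for 6 of 9 members (8 adjusted over the list alone), among them M17 and ABI5 (0.40 ± 0.08), a transcription factor of abscisic acid signalling. Their median log2 change was 5.27, or 3.39 with members at 0 in WT set to their bounds (camera adjusted p = 6.12e-05, and adjusted p = 0.228 with an estimated correlation). Of the 21 members fixed, these 9 passed the filter on low counts. Members near 0 in WT and ref6-1 can pass it only through the libraries where they are high. In comparisons with WT or ref6-1, the direction, share and median of this list are therefore partly set by the filter. Replicate 2 of brm-1 held most counts of CRC (AT4G28520; 12, 134 and 6 in the 3 libraries), PER1 (23, 68 and 0), SESA1 (2, 15 and 2) and OLEO2 (4, 12 and 2). Without it the medians of the 9 were 3.86 and 2.49, and 3 rose, as without WT replicate 3, while 4 rose without WT replicate 1 or 2 or brm-1 replicate 1. Over the 12 members that passed the filter without brm-1 replicate 2, the medians were 2.8 and 1.32.

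Light-harvesting and other photosynthesis genes rose for 12 of 18 members (13 adjusted over the list alone), with LHCB3 at 0.31 ± 0.06 and LHCA1 at 0.25 ± 0.05 (camera adjusted p = 0.000164, and adjusted p = 0.504 with an estimated correlation). Cytokinin genes fell for 6 of 12 members, including the response regulators ARR6 at -1.65 ± 0.13 and ARR16 at -1.08 ± 0.20. Adjusted over the list alone, 6 fell and 2 rose (camera adjusted p = 0.0054, and adjusted p = 0.177 with an estimated correlation). The flavonoid genes FLS1 (-0.62 ± 0.05) and F3H (-0.42 ± 0.06) led 6 of 13 that fell (6 adjusted over the list alone, camera adjusted p = 0.000823, and adjusted p = 0.337 with an estimated correlation). In the circadian clock list of 15, RVE1 (-1.21 ± 0.11), RVE8 (-1.17 ± 0.12), CCA1, PRR5, PRR9 and CDF1 (AT5G62430) fell and FKF1 rose. Adjusted over the list alone, 7 fell and 1 rose (camera adjusted p = 0.000823, and adjusted p = 0.118 with an estimated correlation).

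Among 15 meristem and organ boundary genes, KNAT1 (0.27 ± 0.04), LOB (0.64 ± 0.11), CUC3 (1.14 ± 0.33) and BOP1 rose in brm-1 (4 adjusted over the list alone). The list had a camera adjusted p = 0.0301, and adjusted p = 0.373 with an estimated correlation, and did not pass without WT replicate 2 (0.139) or brm-1 replicate 1 (0.0718) or 2 (0.056, 0.00935 to 0.139 over the libraries left out). CUC1 and CUC2 did not pass, at -0.58 ± 0.38 and 0.62 ± 0.40. The call of CUC3 (edgeR adjusted p = 0.0308) ended without WT replicate 1 (0.102), WT replicate 2 (0.0908), brm-1 replicate 2 (0.103) or brm-1 replicate 3 (0.0601), with 0.016 to 0.103 over the alternatives. In the abscisic acid and cold list, RD29B rose by 2.62 ± 0.27, and 5 of 18 fell, first COR15A at -1.71 ± 0.22 (1 and 7 adjusted over the list alone, camera adjusted p = 0.169). Over all genes, 1960 rose and 2233 fell in brm-1 (4193, edgeR adjusted p under 0.05), of which 232 and 482 changed at least 2-fold. Without brm-1 replicate 2 the number was 2705.

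The second comparison asks the same of REF6. In ref6-1, FLC rose to 18.8 ± 0.643 CPM (SD, n = 3), a log2 change of 2.83 ± 0.14 (SE, edgeR adjusted p = 8.06e-07). Its relative MAF5 rose by 2.69 ± 0.20, FT by 1.29 ± 0.16, SOC1 by 0.38 ± 0.06 and CO by 0.56 ± 0.13. The floral genes SEP3 and SEP4 rose by 1.64 ± 0.13 and 1.18 ± 0.12. SVP, at -0.10 ± 0.04, did not pass. CO was not called without WT replicate 1 (edgeR adjusted p = 0.0753), without ref6-1 replicate 2 (0.0804) or with only the groups compared (0.0514), with 0.0169 to 0.0804 over the alternatives.

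After FLC and MAF5, the largest rises in ref6-1 were those of the nitrate transporter gene NRT2.1 (2.12 ± 0.51), ATHB54 (2.07 ± 0.27), MES8 (2.01 ± 0.32) and the galactosidase gene BGAL7 (1.68 ± 0.37). Falls were led by BPC7, counted 1, 0 and 0 times in ref6-1 against 173 times in WT, a ratio of 169 (95% exact interval 30 to 6730, counting error only). XTH25, a gene of cell-wall enzymes, had 2 counts against 132, a ratio of 64.7 (17.5 to 539). MRD1 (-4.39 ± 0.40), CYP71B18 (-4.19 ± 0.41), the defensin gene PDF1.2c (-3.96 ± 0.64) and MIOX1 (-3.76 ± 0.50) followed. BRM differed by -0.06 ± 0.32 and did not pass. PDF1.2c stood at -3.23 without WT replicate 1 and -5.21 without ref6-1 replicate 3. NRT2.1, at 2.81 without WT replicate 3, (edgeR adjusted p = 0.0292) was not called without WT replicate 1 (0.0731), WT replicate 2 (0.0869), ref6-1 replicate 1 (0.0785) or ref6-1 replicate 2 (0.0996), or with only the groups compared (0.0852), over a range of 0.000507 to 0.0996. BGAL7 (edgeR adjusted p = 0.019) was not called without WT replicate 1 (0.0691), ref6-1 replicate 1 (0.0512) or ref6-1 replicate 2 (0.0651), or with only the groups compared (0.0579), over a range of 0.000297 to 0.0691.

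Flowering time regulators rose for 8 of 26 members in ref6-1, and 0 fell (8 and 2 adjusted over the list alone, camera adjusted p = 7.56e-10, and adjusted p = 0.00153 with an estimated correlation). Of 9 floral organ genes, SEP3, SEP4, PI and SEP1 (AT5G15800) rose. Adjusted over the list alone, 6 were higher and 2 lower (camera adjusted p = 2.5e-07, and adjusted p = 0.00444 with an estimated correlation). The clock genes CDF1 (AT5G62430, -1.18 ± 0.09), RVE8 (-1.66 ± 0.12), CCA1, LHY, PRR9 and RVE1 fell, 6 of 15 members (7 adjusted over the list alone, camera adjusted p = 2.69e-08, and adjusted p = 0.00785 with an estimated correlation). The median of that list was -0.03 and its mean -0.49.

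In the abscisic acid and cold list, RD29A (-0.97 ± 0.08), CBF2 (-1.43 ± 0.27) and 4 others of 18 fell in ref6-1 (10 adjusted over the list alone, camera adjusted p = 1.23e-06, and adjusted p = 0.201 with an estimated correlation). Defensin genes with near-identical copies, PDF1.2 (-2.67 ± 0.48), PDF1.2b (-2.19 ± 0.41) and PDF1.3, fell among 13 jasmonate and ethylene genes (3 adjusted over the list alone, camera adjusted p = 0.0216, and adjusted p = 0.826 with an estimated correlation). PR5 (-0.51 ± 0.09) and PAD4 (-0.45 ± 0.11) fell among 14 salicylate defence genes (3 adjusted over the list alone, camera adjusted p = 0.000905, and adjusted p = 0.649 with an estimated correlation). The auxin list lay higher, with IAA19 (0.75 ± 0.16) the 1 member of 26 that passed (1 adjusted over the list alone, camera adjusted p = 0.0334, and adjusted p = 0.468 with an estimated correlation). Of 18 photosynthesis genes 0 passed (0 adjusted over the list alone), though the list lay higher (camera adjusted p = 0.0254, and adjusted p = 0.826 with an estimated correlation). By camera, the jasmonate list did not pass without ref6-1 replicate 1 (0.105, 4.29e-05 to 0.105 over the libraries left out), nor the auxin list without WT replicate 1 (0.119) or ref6-1 replicate 2 (0.0632, 0.0186 to 0.119). The photosynthesis list did not pass without WT replicate 1 (0.122) or 3 (0.114) or ref6-1 replicate 1 (0.0571) or 2 (0.0513, 0.000138 to 0.122). PDF1.2b was not called with only the groups compared (edgeR adjusted p = 0.0541, 3.04e-06 to 0.0541 over the alternatives). PAD4 was called without ref6-1 replicate 3 but not without any other library compared, nor with only the groups compared (adjusted p from 0.00353 to 0.0961 over the alternatives), and IAA19 was not called without WT replicate 1 (edgeR adjusted p = 0.0587) or ref6-1 replicate 2 (0.0659, 0.00266 to 0.0659 over the alternatives).

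CUC1, which sets organ boundaries, fell by 2.30 ± 0.47 in ref6-1 (edgeR adjusted p = 0.0145), but was not called without WT replicate 1 (0.063, 0.00838 to 0.063 over the alternatives). ABI5 fell by 0.32 ± 0.08 (edgeR adjusted p = 0.0365), a call kept without WT replicate 3 and lost without any other library compared, with DESeq2 (0.119), with limma-voom (0.0542) and with only the groups compared (0.0728), over a range of 0.0228 to 0.135. KNAT1, CUC2 and CUC3 did not pass, at 0.14 ± 0.04, 0.42 ± 0.41 and 0.28 ± 0.35. In all, 514 genes rose and 1242 fell in ref6-1 (1756, edgeR adjusted p under 0.05), 61 and 341 of them at least 2-fold. The total was 862 without WT replicate 1, 1008 without ref6-1 replicate 1 and 934 without ref6-1 replicate 2.

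**Figure D2:**
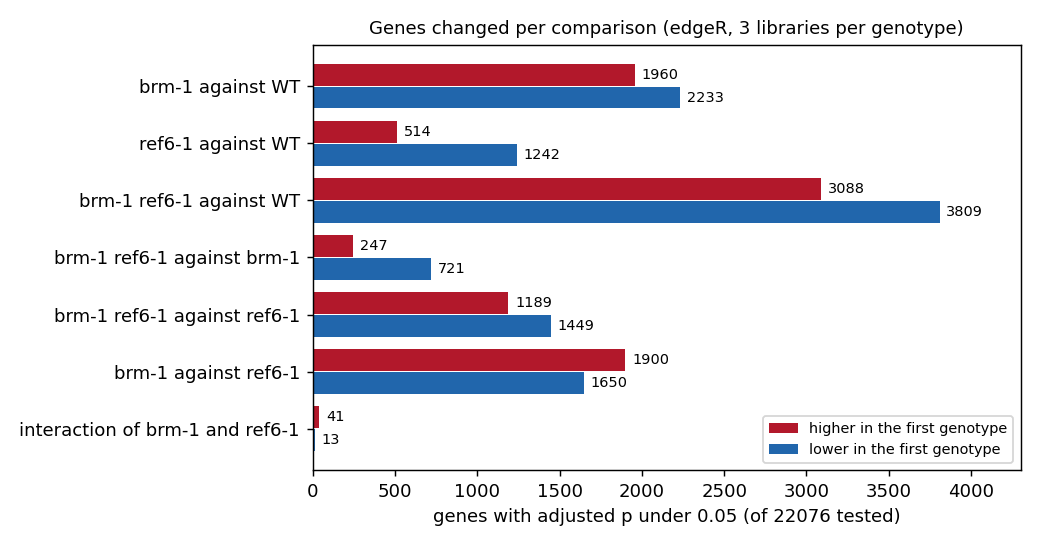
Number of genes with an edgeR adjusted p under 0.05 in each comparison (x axis, of 22076 tested), split into genes higher and lower in the genotype named first. For the interaction, higher means above the sum of the single-mutant log2 changes, and the combined mutant against WT had the longest bars, with 3088 higher and 3809 lower.

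In seedlings with both mutations FLC reached 37.8 ± 1.78 CPM (SD, n = 3), a log2 change of 3.83 ± 0.13 against WT (SE, edgeR adjusted p = 1.6e-08). FT rose by 1.77 ± 0.15, CO by 1.08 ± 0.12, SOC1 by 0.41 ± 0.06 and SEP3 by 2.98 ± 0.12, while SVP changed by -0.27 ± 0.04. The seed storage gene CRC (AT4G28520), with 0 counts in every WT library and 123, 475 and 123 in the combined mutant, was at least 259-fold higher (against 3 counts over the WT group), or at least 131-fold without brm-1 ref6-1 replicate 2. CRA1 rose by 7.30 ± 1.05 and M17 by 5.01 ± 0.55 (5.86 without WT replicate 2). FOP1 and PER1, a peroxiredoxin gene of seeds, rose with ratios of 111 (95% exact interval 30.3 to 922) and 90.5 (24.7 to 753, counting error only). BHLH100, an iron-deficiency regulator, rose by 5.58 ± 1.49, on counts of 207, 21 and 11 against 0, 3 and 2 in WT.

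The largest falls in brm-1 ref6-1 were those of the receptor-like kinase gene CRK23 (-6.05 ± 0.82), the sucrose carrier gene SUC7 (-6.02 ± 1.33), CYP71A20 (-5.57 ± 0.53), ARD3 (-5.04 ± 0.46), the carboxypeptidase-like scpl22 (-5.03 ± 1.29) and the phosphate transporter gene PHT1;7 (-4.51 ± 0.60). CRK23 and SUC7 had 4 counts each in the combined mutant, all in replicate 2 and all in replicate 3 respectively, so without those libraries their fitted falls (-9.66 and -9.63) are set against 0 counts and are no bound. CYP71A20 stood at -6.46 without brm-1 ref6-1 replicate 3. The call of scpl22 ended without brm-1 ref6-1 replicate 1 (edgeR adjusted p = 0.06, 3.7e-05 to 0.06 over the alternatives). PER1 (edgeR adjusted p = 0.0121) was not called without WT replicate 1 or 2 (0.0528 each, 0.000224 to 0.0528 over the alternatives). BHLH100 was not called without WT replicate 1 (edgeR adjusted p = 0.0671) or 3 (0.0529), with only the groups compared (0.0664) or with limma-voom (adjusted p = 0.104), over a range of 0.00239 to 0.104, and rose by 3.27 without brm-1 ref6-1 replicate 1.

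Salicylate defence genes fell for 9 of 14 members in brm-1 ref6-1 (11 adjusted over the list alone), first WRKY70 at -0.56 ± 0.09 and PAD4 at -0.64 ± 0.11 (camera adjusted p = 0.000164, and adjusted p = 0.4 with an estimated correlation). Of 9 seed maturation genes, 8 rose (8 adjusted over the list alone), M17 and ABI5 (0.64 ± 0.08) first. Their median log2 change was 6.25, or 5.12 with members at 0 in WT set to their bounds (camera adjusted p = 4.69e-07, and adjusted p = 0.161 with an estimated correlation). These medians of the 9 were 7.69 and 5.35 without WT replicate 2, and 5.76 and 4.73 without WT replicate 3. Over the 11 and 12 members that then passed the filter, they were 6.31 and 4.6, and 4.66 and 4.43. FLS1 (-0.53 ± 0.05), F3H (-0.41 ± 0.06) and 5 others of 13 flavonoid genes fell (8 adjusted over the list alone, camera adjusted p = 0.000313, and adjusted p = 0.4 with an estimated correlation). Photosynthesis genes rose for 10 of 18 members (12 adjusted over the list alone), first LHCA3 at 0.22 ± 0.06 (camera adjusted p = 0.00922, and adjusted p = 0.691 with an estimated correlation). That list did not pass without brm-1 ref6-1 replicate 1 (camera adjusted p = 0.069, 0.000235 to 0.069 over the libraries left out). LHCA3 was not called without WT replicate 1 (edgeR adjusted p = 0.0538) or brm-1 ref6-1 replicate 1 (0.0647), with 0.00514 to 0.0647 over the alternatives.

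In the clock list, RVE8 (-1.92 ± 0.13), CDF1 (AT5G62430, -1.17 ± 0.09) and 6 others of 15 fell (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 5.95e-05, and adjusted p = 0.0424 with an estimated correlation). Flowering time regulators rose for 10 and fell for 4 of 26, with FLC and FT first (10 and 5 adjusted over the list alone, camera adjusted p = 0.000229, and adjusted p = 0.0201 with an estimated correlation). SEP3 and SEP4 (1.33 ± 0.12) led the 5 floral organ genes of 9 that rose, and SHP1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 4.69e-07, and adjusted p = 0.00822 with an estimated correlation). KNAT1 (0.63 ± 0.04), LOB, BOP1 and CUC3 (1.07 ± 0.34) rose among 15 meristem and boundary genes. CUC1, counted 22, 13 and 17 times in WT and 0 times in every combined-mutant library, was at least 16.1-fold lower against 3 counts over the group. That list (4 and 1 adjusted over the list alone) lay higher by the test and the median of 0.31 but not by the mean of -0.13 (camera adjusted p = 0.0299, and adjusted p = 0.4 with an estimated correlation), and did not pass without WT replicate 2 (0.0858) or brm-1 ref6-1 replicate 2 (0.0524, 0.0134 to 0.0858 over the libraries left out). CUC2 did not pass, at 0.83 ± 0.40. The call of CUC3 (edgeR adjusted p = 0.0289) ended without WT replicate 1 (0.0908), WT replicate 2 (0.0857) or brm-1 ref6-1 replicate 1 (0.112, 0.019 to 0.112 over the alternatives).

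The 12 remaining lists did not pass as sets in brm-1 ref6-1, although members did. In the brassinosteroid list 4 rose and 4 fell of 11, first BR6OX1 at -2.57 ± 0.29 (5 and 4 adjusted over the list alone, camera adjusted p = 0.701, with the median of 0.05 and the test up and the mean of -0.22 down). In the gibberellin list 3 rose and 1 fell of 15, first GASA6 at 0.48 ± 0.07 (3 and 1 adjusted over the list alone, camera adjusted p = 0.433, with the median of 0.09 and the test up and the mean of -0.14 down). Among abscisic acid and cold genes 2 rose and 8 fell of 18, first RD29A at -0.86 ± 0.08 (2 and 9 adjusted over the list alone, camera adjusted p = 0.0557). Cytokinin genes rose for 1 and fell for 3 of 12, first CKX4 at -1.10 ± 0.11 (1 and 4 adjusted over the list alone, camera adjusted p = 0.0954). Auxin genes rose for 3 and fell for 4 of 26, first SAUR9 at -1.39 ± 0.27 (3 and 4 adjusted over the list alone, camera adjusted p = 0.933). KN (0.21 ± 0.05), a cytokinesis gene, and 3 others of 10 cell cycle genes rose (4 adjusted over the list alone, camera adjusted p = 0.0928).

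Of 13 jasmonate and ethylene genes, PDF1.2 fell (-1.93 ± 0.45, 1 adjusted over the list alone, camera adjusted p = 0.332). Glucosinolate genes rose for 2 and fell for 2 of 12, first CYP79B2 at -0.33 ± 0.07 (3 and 2 adjusted over the list alone, camera adjusted p = 0.701). Expansin and xyloglucan enzyme genes rose for 2 and fell for 4 of 15, first EXPA5 at -0.50 ± 0.08 (2 and 4 adjusted over the list alone, camera adjusted p = 0.644). The root markers WOX5 (1.09 ± 0.27) and IRT1 rose among 16 (2 adjusted over the list alone, camera adjusted p = 0.967), with a median of -0.07 against a mean of 0.33 and a test up. IRT1, counted 44, 10 and 0 times against 0, 1 and 0 in WT, was not called without any 1 of the WT libraries, without brm-1 ref6-1 replicate 1 or with limma-voom (adjusted p = 0.16, 0.0016 to 0.16 over the alternatives). ELF6 (-0.13 ± 0.03) and MEA fell among 11 Polycomb and demethylase genes (2 adjusted over the list alone, camera adjusted p = 0.933). CHR23 (-0.33 ± 0.05) and CHR12 fell among 9 SWI/SNF genes (2 adjusted over the list alone, camera adjusted p = 0.701). ELF6 was not called without brm-1 ref6-1 replicate 2 (0.0507) or with DESeq2 (0.0827), with adjusted p from 0.00911 to 0.0827 over the alternatives. Over all genes, 3088 rose and 3809 fell (6897, edgeR adjusted p under 0.05), with 291 and 1057 at least 2-fold. Without replicate 3 of the combined mutant, the library with 438 BRM counts, 6428 genes passed, 5873 of them also among the 6897. The number was 4692 without brm-1 ref6-1 replicate 1, 5184 without WT replicate 1 and 5167 with DESeq2.

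**Figure D3:**
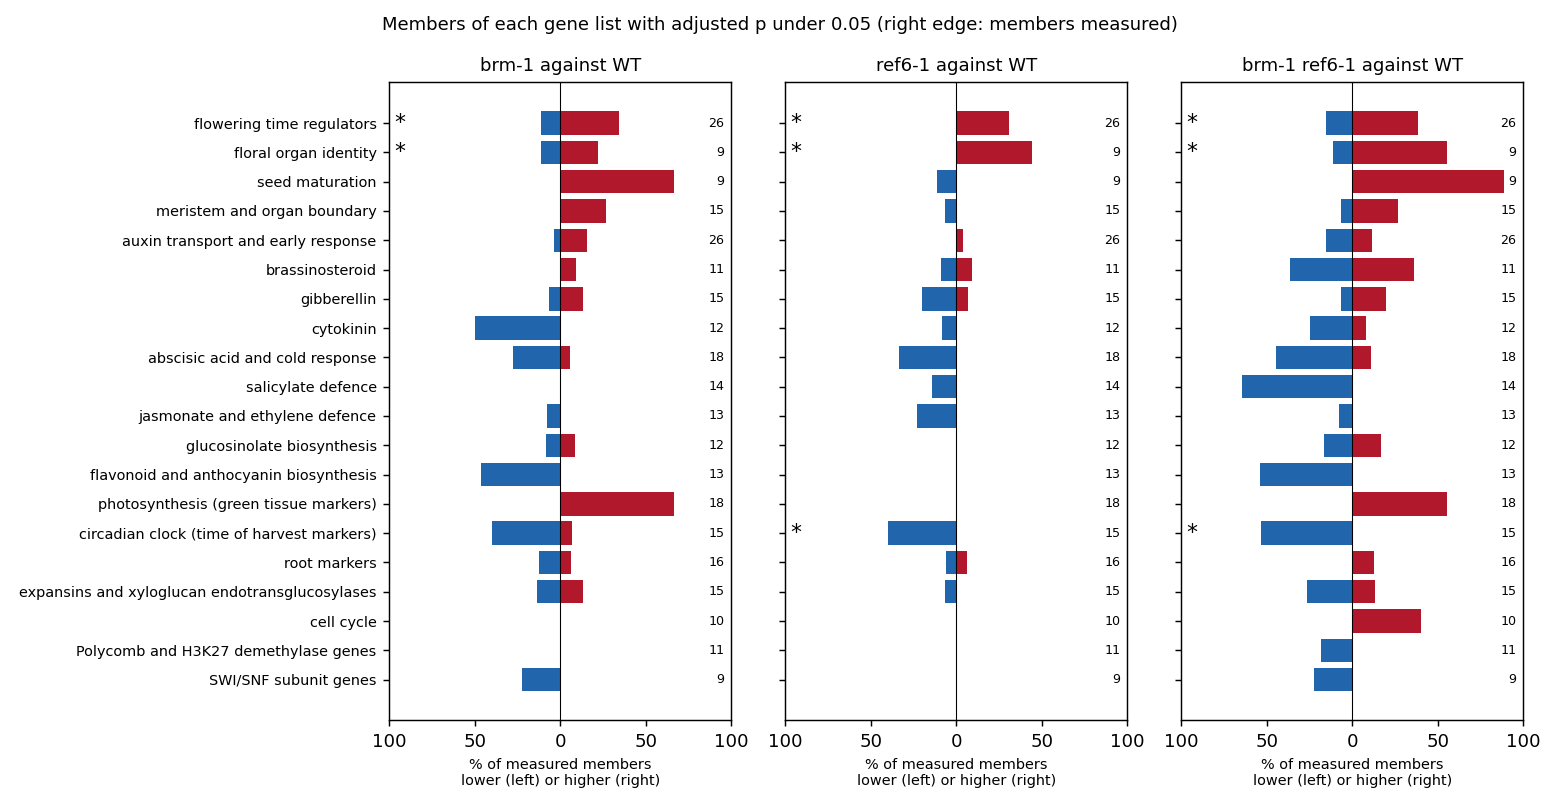
Percentage of the measured members of each of 20 gene lists that were higher (right, red) or lower (left, blue) than WT at an edgeR adjusted p under 0.05, in 3 mutant genotypes, where the number at the right edge is the members measured and an asterisk marks a camera adjusted p under 0.05 with an estimated correlation. Salicylate defence genes fell for 0 of 14 members in brm-1, 2 in ref6-1 and 9 in brm-1 ref6-1. Set directly against ref6-1, the combined mutant had 0 of these 14 called (camera adjusted p = 0.0644).

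To ask whether BRM and REF6 affect the same transcripts, the calls of the single mutants were set side by side. FLC, ATHB54, MAF5, SEP3, FT and the anion channel gene SLAH1 led the 254 genes that rose in both, with MAF5 at 2.01 ± 0.21 in brm-1 and ATHB54 at 2.33 ± 0.27. MRD1, CRK23, HEI10, GLYI7, BBX31 and PUB19 led the 449 that fell in both, with CRK23 at -3.02 ± 0.57 in brm-1 and -3.53 ± 0.61 in ref6-1, and HEI10 at -2.94 ± 0.23 and -2.78 ± 0.23. Without ref6-1 replicate 3, CRK23 stood at -4.62 in ref6-1. MRD1 and HEI10 overlap on chromosome 1, so reads of the shared stretch may be counted for either gene. A further 74 genes changed in opposite directions, 53 of them higher in brm-1 and lower in ref6-1, among them RD29B (2.62 ± 0.27 in brm-1) and ABI5.

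Independent lists of these sizes would share 45.6 rising and 125.6 falling genes. Both comparisons use the same WT libraries, and across 10 simulations of unchanged groups against these controls at most 1 gene was shared. With no gene changed there, few could be called in either comparison, so that number is no expectation for the shared genes. The correlation of log2 changes across genes, which are not independent replicates, was 0.492 in the simulations and 0.354 observed, and the covariance was 0.0196 and 0.0768, a difference of 0.0572. With 3 WT libraries the controls could not be split, so part of the excess over independent lists may come from sharing them. The 703 shared genes became 313 without WT replicate 1, 467 without brm-1 replicate 2, 468 without ref6-1 replicate 1 and 394 without ref6-1 replicate 2. SLAH1 and BBX31 lost their calls without WT replicate 1 in both mutants (edgeR adjusted p = 0.154 and 0.0724 in brm-1, 0.157 and 0.0774 in ref6-1), and also without brm-1 replicate 2 or 3 or ref6-1 replicate 1, 2 or 3. They lost them without WT replicate 3 (SLAH1) or 2 (BBX31) too, and SLAH1 with only the groups compared (0.0511 and 0.0575), with 0.0144 to 0.157 and 0.00402 to 0.0886 over their alternatives in both mutants.

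**Figure D4:**
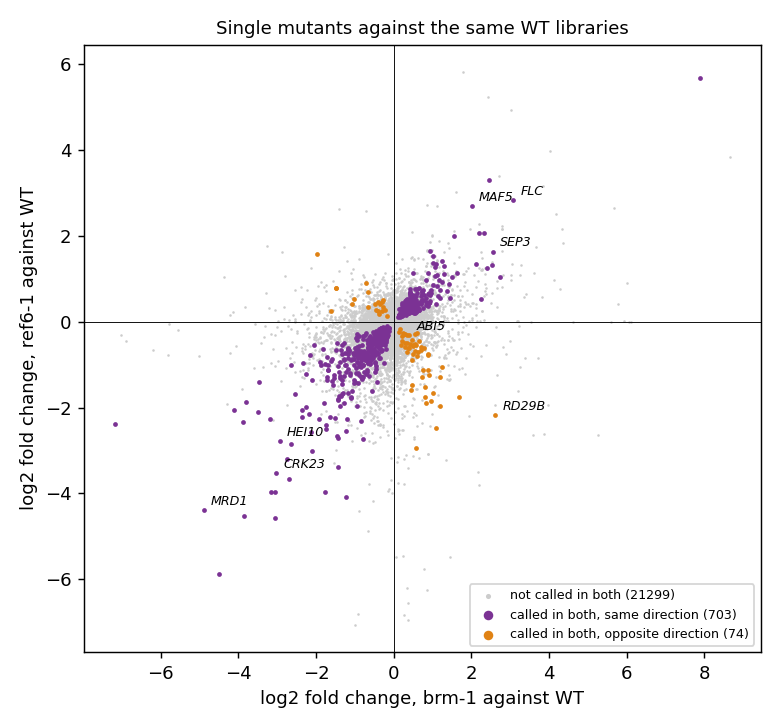
Log2 fold change of each of 22076 genes in brm-1 (x axis) and in ref6-1 (y axis) against the same 3 WT libraries, where purple points passed in both in the same direction (703) and orange points in opposite directions (74). FLC, MAF5 and SEP3 lie in the upper right and MRD1, HEI10 and CRK23 in the lower left.

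Against brm-1, the combined mutant had more FLC by 0.76 ± 0.10 (edgeR adjusted p = 0.00152, n = 3 per group), more SEP4 by 0.96 ± 0.11 and more KNAT1 by 0.36 ± 0.04. The salicylate synthesis gene ICS1 (-1.19 ± 0.17), the brassinosteroid gene DWF4 (-0.59 ± 0.08), the cytokinin oxidase gene CKX4 (-0.89 ± 0.11), RD29A (-0.60 ± 0.09) and the clock gene PRR9 (-1.01 ± 0.16) fell. These 8 are the best members of their lists, and the best members of 5 more lists passed but lost the call without at least 1 library. The largest rises were MRD1 (2.75 ± 0.47), the homeobox gene WOX2 (2.00 ± 0.35), CKX3 (1.64 ± 0.37) and AGL19 (1.59 ± 0.27). The largest falls were XTH25 (-4.50 ± 0.79), the acid phosphatase gene PAP23 (-4.21 ± 0.67), BPC7 (-3.77 ± 0.50) and CRK37 (-3.63 ± 0.77), which stood at -6.81, -6.00, -5.41 and -4.92 without brm-1 ref6-1 replicate 3. BRM (1.74 ± 0.89) did not pass and stood at -0.13 without that library, and REF6 fell by 0.19 ± 0.05 (edgeR adjusted p = 0.0403). REF6 kept no call when any 1 library compared was left out, nor with DESeq2 (adjusted p = 0.0188 to 0.125 over the alternatives), and CKX3, among the left-out libraries, kept its edgeR call only without brm-1 ref6-1 replicate 1 (0.00755 to 0.1 over the alternatives). MRD1 lost its edgeR call without brm-1 replicate 3 (0.0519, 1.61e-06 to 0.0684), XTH25 without brm-1 ref6-1 replicate 2 (0.052, 1.32e-06 to 0.0648), and CRK37 without brm-1 replicate 1 or 3 or brm-1 ref6-1 replicate 1 or 2 (5.56e-05 to 0.0893). With limma-voom, CKX3, MRD1, XTH25 and CRK37 were not called.

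Of 14 salicylate genes, ICS1, PAD3 and CYP71A13 fell against brm-1 (10 adjusted over the list alone, camera adjusted p = 1.51e-10, and adjusted p = 0.337 with an estimated correlation). The floral organ list lay higher, with PI, SEP3 and SEP4 up and AG and SHP1 down of 9 (4 and 2 adjusted over the list alone, camera adjusted p = 0.00165, and adjusted p = 0.103 with an estimated correlation). The seed maturation list lay higher with 0 of 9 passing (6 and 1 adjusted over the list alone, camera adjusted p = 0.00165, and adjusted p = 0.461 with an estimated correlation), with a median of 1.37, or 2.39 and 4 passing without brm-1 replicate 2. In total 247 genes rose and 721 fell (968, edgeR adjusted p under 0.05). Without brm-1 replicate 1 or 3 the numbers were 468 and 458, and without brm-1 ref6-1 replicate 1 or 2 they were 480 and 364.

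Against ref6-1, the combined mutant had more FLC by 1.00 ± 0.10 (edgeR adjusted p = 9.39e-05, n = 3 per group), more SEP3 by 1.34 ± 0.10, more ABI5 by 0.96 ± 0.08 and more KNAT1 by 0.49 ± 0.04. RD29B, a gene induced by abscisic acid, rose by 4.11 ± 0.37 (5.32 without ref6-1 replicate 1). EXPA5 (-0.65 ± 0.08), ARR6 (-1.05 ± 0.13) and FLS1 (-0.37 ± 0.05) fell. These 8 are the best members of their lists, and the best members of 7 more lists passed, BRM itself among them, 3 of which lost the call without at least 1 library. The largest rises were those of PER1, with 168 counts against 0 (at least 59.1-fold, against 3 counts over the group), BHLH100, with 239 counts against 1 (a ratio of 252, 95% exact interval 44.8 to 10000, or 50.5 without brm-1 ref6-1 replicate 1), CRA1 (7.27 ± 1.05) and CRC (AT4G28520, 7.16 ± 1.69). The largest falls were those of CYP71A20 (-4.92 ± 0.55), ARD3 (-4.48 ± 0.48), BRM (-3.97 ± 0.46) and the receptor-like kinase gene CRK4 (-3.65 ± 0.73). Without brm-1 ref6-1 replicate 3, CYP71A20 stood at -5.82 and BRM at -5.84. REF6 differed by -0.02 ± 0.05 and did not pass. PER1 lost its edgeR call without ref6-1 replicate 2 (0.0517) or brm-1 ref6-1 replicate 1 (0.0522) or 2 (0.0569, 0.00113 to 0.0569 over the alternatives), and BHLH100 without any ref6-1 replicate, with limma-voom or with only the groups compared (0.000628 to 0.108). CRC kept its edgeR call, among the left-out libraries, only without brm-1 ref6-1 replicate 3, and lost it with limma-voom and with no filter (0.00227 to 0.15). CRA1 lost it with limma-voom (0.0596, 5.41e-09 to 0.0596), and CRK4 without brm-1 ref6-1 replicate 1 (0.0562) and with limma-voom (0.0687, 1.61e-06 to 0.0687).

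Seed maturation genes rose against ref6-1 for 8 of 9 members (8 adjusted over the list alone, camera adjusted p = 1.13e-11, and adjusted p = 0.202 with an estimated correlation), and for 5 without ref6-1 replicate 2. Flavonoid genes fell for 6 of 13 (8 adjusted over the list alone, camera adjusted p = 8.37e-06, and adjusted p = 0.325 with an estimated correlation). In the floral organ list PI and SEP3 rose and SHP1 fell of 9 (2 and 1 adjusted over the list alone, camera adjusted p = 0.0277, and adjusted p = 0.204 with an estimated correlation). The meristem list, with 4 up and CUC1 down of 15 (4 and 1 adjusted over the list alone), lay higher by the test and the median of 0.17 but not by the mean of -0.07 (camera adjusted p = 0.0277, and adjusted p = 0.381 with an estimated correlation). By camera, the floral list did not pass without ref6-1 replicate 1 (0.0879) or brm-1 ref6-1 replicate 2 (0.0501) or 3 (0.0513, 0.0269 to 0.0879 over the libraries left out), nor the meristem list without ref6-1 replicate 2 (0.0572) or brm-1 ref6-1 replicate 2 (0.0555, 0.00669 to 0.0572). In total 1189 genes rose and 1449 fell (2638, edgeR adjusted p under 0.05), and 1695 passed without brm-1 ref6-1 replicate 2.

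Set against each other, brm-1 had more RD29B than ref6-1 (9.54 ± 1.24 against 0.329 ± 0.334 CPM, SD, n = 3), a log2 difference of 4.80 ± 0.35 (SE, edgeR adjusted p = 4.19e-06), or 6.00 without ref6-1 replicate 1. SEP3 (0.92 ± 0.10), ABI5 (0.72 ± 0.08) and DWF4 (0.57 ± 0.08) were also higher in brm-1, and ARR6 (-1.58 ± 0.13), AGL24 (-1.80 ± 0.17), FLS1 (-0.46 ± 0.05) and XTH17 (-1.10 ± 0.17) were lower. These 8 are the best members of their lists, and the best members of 10 more lists passed, BRM and REF6 themselves among them. Of these 10, 4 lost the call without at least 1 library, REF6 included. BPC7 had 220 counts in brm-1 against 1 in ref6-1 (a ratio of 220, 95% exact interval 39 to 8720) and XTH25 had 222 against 2 (111, 30.3 to 921), followed by CRA1 (5.90 ± 1.16, or 4.89 without brm-1 replicate 2) and FOP1 (5.11 ± 0.54). BRM (-5.71 ± 0.56), CYP71A20 (-5.53 ± 0.59), ARD3 (-3.50 ± 0.42) and CYP716A1 (-2.98 ± 0.37) were lowest in brm-1 relative to ref6-1. REF6 was higher by 0.17 ± 0.05 (edgeR adjusted p = 0.0255), a call lost without any of the brm-1 replicates, without ref6-1 replicate 1 or 3 and with DESeq2 (0.0142 to 0.0961 over the alternatives). CRA1 was not called with limma-voom (adjusted p = 0.13, 3.58e-06 to 0.13 over the alternatives).

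Between the single mutants, seed maturation genes were higher in brm-1 for 6 of 9 (7 adjusted over the list alone, camera adjusted p = 0.000166, and adjusted p = 0.627 with an estimated correlation), with a median of 4.24, or 3.03 with members at 0 set to their bounds. Without brm-1 replicate 2 the medians of the 9 were 2.34 and 1.58 and 2 passed, as without ref6-1 replicate 1 or 3, while 3 passed without brm-1 replicate 1 and 4 without ref6-1 replicate 2. Over the 12 members that passed the filter without brm-1 replicate 2, the medians were 1.78 and 1.5. Flavonoid genes were lower for 4 of 13 (5 adjusted over the list alone, camera adjusted p = 0.00591, and adjusted p = 0.627 with an estimated correlation). The salicylate genes PR5, ICS1 and CYP71A13 were higher among 14 (3 adjusted over the list alone, camera adjusted p = 0.0199, and adjusted p = 0.633 with an estimated correlation). That list did not pass without brm-1 replicate 3 (camera adjusted p = 0.058) or ref6-1 replicate 1 (0.122, 0.00228 to 0.122 over the libraries left out). ICS1 (edgeR adjusted p = 0.0127) was not called with only the groups compared (0.0577, 4.37e-05 to 0.0577 over the alternatives). Over all genes 1900 were higher and 1650 lower in brm-1 (3550, edgeR adjusted p under 0.05), and 2450 passed without ref6-1 replicate 2.

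Whether the combined mutant departs from the sum of the single-mutant log2 changes was tested as an interaction. FLC lay below that sum, at -2.07 ± 0.18 (edgeR adjusted p = 0.00043, n = 3 per group). MAF5, at -3.33 ± 0.27, had 2.50 ± 0.232 CPM in WT, 10.1 ± 0.0775 in brm-1, 16.2 ± 2.49 in ref6-1 and 6.46 ± 1.78 in the combined mutant (SD, n = 3). SEP3 (-1.21 ± 0.17) and the endoglucanase gene GH9B13 (-0.77 ± 0.09) also lay below the sum. MRD1 and HEI10, which overlap on chromosome 1, lay above it at 7.14 ± 0.62 and 3.89 ± 0.34, followed by the nucleolin gene NUC-L2 (1.84 ± 0.26) and LEA7 (1.62 ± 0.29). MRD1 had 50.3 ± 0.902 CPM in WT, 1.68 ± 0.306 in brm-1, 2.38 ± 0.786 in ref6-1 and 11.4 ± 6.38 in the combined mutant. The clock gene RVE1 lay above the sum at 0.95 ± 0.16. BRM (1.81 ± 0.94) and REF6 (-0.03 ± 0.07) did not pass, and without brm-1 ref6-1 replicate 3 BRM stood at -0.07.

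Flowering time regulators lay below the sum as a list, with FLC and MAF5 passing of 26 (7 adjusted over the list alone, camera adjusted p = 1.71e-12, and adjusted p = 0.000643 with an estimated correlation). Camera also placed the floral (adjusted p = 0.0125), auxin (8.18e-06), salicylate (0.0125) and photosynthesis (0.000733) lists below the sum. It placed the cytokinin (adjusted p = 0.0229), abscisic acid and cold (2.19e-05), jasmonate (0.00686), clock (0.000414) and root (0.0155) lists above it. None of these 9 held with an estimated correlation, at adjusted p = 0.0962, 0.0744, 0.585 and 0.585 for the first 4 and 0.199, 0.199, 0.585, 0.0782 and 0.585 for the others. Already with a correlation of 0.01, the salicylate list did not pass without WT replicate 1 or 3, brm-1 replicate 3, ref6-1 replicate 2 or 3 or brm-1 ref6-1 replicate 1 (camera adjusted p = 0.0529 to 0.235 there, 9.78e-06 to 0.235 over the libraries left out). The root list did not pass without WT replicate 1 or 3, brm-1 replicate 3 or ref6-1 replicate 3 (0.0563 to 0.181, 0.000232 to 0.181). The cytokinin list did not pass without WT replicate 1, ref6-1 replicate 1 or brm-1 ref6-1 replicate 3 (0.0537 to 0.116, 0.00711 to 0.116), nor the jasmonate list without ref6-1 replicate 1 (0.0938) or brm-1 ref6-1 replicate 3 (0.0741, 1.48e-06 to 0.0938). Of their members, SEP3 passed in the floral list and RVE1 and CDF1 (AT5G62430) in the clock list. Adjusted over the list alone, 1 floral and 5 auxin genes lay lower, 3 cytokinin genes higher and 1 lower, 3 jasmonate and 3 clock genes higher, 1 root gene lower, and 0 in the other 3 lists. The root list had a median of 0.26 and a mean of -0.12.

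In all 41 genes lay above the sum and 13 below (54, edgeR adjusted p under 0.05). Among them were 30 of the genes that fell in both single mutants and 7 of those that rose in both. For genes that fall strongly in both, the sum can lie below what the counts can show. WT also enters the single-mutant changes and the interaction with opposite signs. Error in the shared WT libraries can therefore move such genes to the opposite side of the sum. The number was 17 and 23 without WT replicate 1 or 2, 21 without brm-1 replicate 2 or 3, 12 without ref6-1 replicate 2, 15 without brm-1 ref6-1 replicate 2, and 95 with DESeq2. LEA7 lost its edgeR call when any 1 of the 12 libraries was left out (0.00115 to 0.14 over the alternatives), and RVE1 when any but ref6-1 replicate 1 or 3 was (0.000665 to 0.0963). NUC-L2 (edgeR adjusted p = 0.0609) and SEP3 (0.0595) lost theirs without ref6-1 replicate 2, and also with limma-voom (2.99e-05 to 0.0768 and 3.08e-07 to 0.0618 over the alternatives).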

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

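Among the tests in this part, only that of additive effects on the clock genes was chosen after its result was seen. FLC lay below the sum of the single-mutant log2 changes in brm-1 ref6-1 (-2.07 ± 0.18), as did MAF5 (-3.33 ± 0.27), SEP3 (-1.21 ± 0.17) and GH9B13 (-0.77 ± 0.09). MRD1 (7.14 ± 0.62), HEI10 (3.89 ± 0.34), NUC-L2 (1.84 ± 0.26), LEA7 (1.62 ± 0.29) and RVE1 (0.95 ± 0.16) lay above it. These genes stand out because they passed the interaction test of edgeR (54 genes at an adjusted p under 0.05), though LEA7 lost its call without any 1 of the 12 libraries (0.00115 to 0.14 over the alternatives), RVE1 without any 1 of 10 (0.000665 to 0.0963), and NUC-L2 (0.0609, 2.99e-05 to 0.0768) and SEP3 (0.0595, 3.08e-07 to 0.0618) without ref6-1 replicate 2. Of 100 splits of the 12 libraries into groups of 3, only the real one gave as many genes, and the highest other gave 5. The other splits mix genotypes within a group, which widens the spread there and lowers the number of calls. They therefore cannot decide whether chance gave the count of 54. For gene lists, 2 of 100 splits gave at least the 10 lists of the real groups, and the highest other gave 11. For genes changed in both single mutants, 2 of 100 splits gave at least 703. The other one gave 1432, with the 3 brm-1 libraries together as the shared control and WT and ref6-1 libraries mixed. The next highest gave 217. Both mixed groups differ in genotype from that shared control, which may by itself give shared calls. The splits mix genotypes here too, so they do not decide what gave the 703 genes.

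Each pair of genotypes allows only 10 splits of its 6 libraries, too few for a share under 0.05. The real split called 4193, 1756, 6897, 968, 2638 and 3550 genes (brm-1, ref6-1 and the combined mutant against WT, the combined mutant against brm-1 and against ref6-1, brm-1 against ref6-1), as the 1 split in each pair with that many, and the highest others called 0, 0, 0, 0, 3 and 0. For lists, in the same order, the real split called 8, 8, 8, 3, 4 and 3, the highest others called 9, 7, 8, 5, 7 and 7, and 2, 1, 2, 8, 5 and 8 splits gave at least as many. In the last 3 comparisons, those between mutants, the other splits called medians of 4, 3 and 4 lists. The number of lists called between mutants therefore does not set the real groups apart. Other splits mix the genotypes unevenly and may keep part of a genotype difference, so they do not decide about single lists.

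Dawn-phased core clock genes, RVE1 among them, had median log2 changes of -0.74 in brm-1, -1.24 in ref6-1 and -1.23 in brm-1 ref6-1. Effects of the 2 mutations that simply add up would leave the interaction near 0, and its median over 15 dawn-phased clock and output genes was 0.34 (bootstrap 95% interval over genes 0.05 to 0.85, with 12 of 15 above 0), with 0.77 over the 6 core clock genes and 0.07 over the 9 output genes. A WT harvest at another hour than the mutants may also lower dawn genes, and it would then raise evening-phased ones and, as WT enters the contrast, the interaction of dawn genes. Medians of the evening-phased genes were -0.03, 0.01 and 0.01 (0.01 over the 3 mutants), while dawn-phased output genes stood at -0.15, -0.25 and -0.42. Of 9 evening-phased genes, 1, 0 and 2 were called lower and 0 higher, so the called ones do not go with a rise. As the evening medians lay near 0, harvest time and genotype cannot be told apart for these genes. While the harvest hour is undecided, effects that add up cannot be told apart from those that do not. An effect of the mutations on the clock stays open as an untested biological hypothesis.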

How the results depend on the processing

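Leaving out brm-1 ref6-1 replicate 3 for comparisons without that genotype was chosen after the data were seen, and gave 4140 genes in brm-1, 1606 in ref6-1, 3466 between the single mutants and 668 shared. Leaving aside BRM in brm-1 and REF6 in ref6-1 against WT, of 3265 alternative values for 239 results on single genes 2986 kept direction and side of the threshold, 273 fell below it and 6 changed sign, and of the latter none was called with all libraries. In the order brm-1, ref6-1 and the combined mutant against WT, the combined mutant against brm-1 and against ref6-1, brm-1 against ref6-1, interaction and genes shared by the single mutants, a 2-fold minimum left 714, 402, 1348, 303, 534, 756, 16 and 102 genes, and an adjusted p under 0.01 left 2138, 622, 3835, 279, 1194, 1788, 12 and 217, as stricter thresholds must. With an estimated inter-gene correlation 2, 3, 3, 0, 0, 0 and 1 gene lists passed in the first 7. DESeq2 called 95 interaction genes, and limma-voom 2 gene lists against ref6-1 in the combined mutant, and the cause was not tested. Leaving out 1 library at a time gave 2705 to 4140 genes in brm-1, 862 to 1763 in ref6-1, 4692 to 6428 in the combined mutant against WT, 364 to 902 and 1695 to 2494 in the combined mutant against brm-1 and ref6-1 (with 3 to 6 and 2 to 6 gene lists), 2450 to 3466 between the single mutants, 12 to 55 for the interaction and 313 to 721 shared, and fewer libraries also give the test less to work with. Over the same omissions REF6 ran from -0.04 to 0.06 in brm-1, -0.21 to -0.11 in ref6-1, -0.04 to 0 in the combined mutant against ref6-1 and -0.08 to 0.02 in the interaction. BRM ran from -0.13 to 2.21 in the combined mutant against brm-1 and from -0.07 to 2.27 in the interaction, and CUC3 from -0.28 to 0.51 in ref6-1. Scaling with the size factors of DESeq2 changed no call among the single genes. For the interaction a fit of only the groups compared is the full fit, and the DESeq2 adjusted p of BRM was not available. Changes that depth could not show are not absent, as 71 of 100 simulated 1.5-fold changes were called for brm-1 against WT.

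With the replicate number as a block, 4437, 2023, 7196, 1053, 2831, 3834, 72 and 831 genes passed in the same order, and 3 of the single-gene calls were lost. Each of these numbers of genes was higher than without the block, so a partial pairing of the samples by replicate number stays open. Correlations of same-numbered libraries ran from -0.19 to 0.29, with 6 of 18 over 0.1, and 6 of 12 libraries correlated best with their own number.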

Other observations

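All tests in this part were chosen after the result was seen. Genes named as cysteine-rich receptor-like kinases (CRK), a family of plasma membrane kinases many of which respond to pathogens, were lower in brm-1 ref6-1 than in WT for 25 of 37 measured members and higher for 2, with a median log2 change of -0.86. In ref6-1, 13 of 37 were lower and 0 higher (median -0.49), and in brm-1 5 were lower and 3 higher (median 0). The family was picked because CRK23, CRK4 and CRK37 were among the largest falls, and without these 3 the median in the combined mutant was -0.65. Whether the family falls as a set there stays an open hypothesis, since camera with an estimated correlation, adjusted over the 3 mutants, gave p = 0.071 without them and p = 0.0632 with them. Members lie close in sequence and may share reads, so single genes of the family are uncertain, and the difference between genotypes was not tested for the family.

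Replicate 3 of brm-1 ref6-1 held 14.7% of the WT level of BRM, against 2.1% and 1.2% in replicates 1 and 2. Transcript of the brm-1 allele alone, and reads from the ref6-1 libraries, are both argued against by 5 loci that brm-1 keeps, chosen for levels of at most 5% of WT in ref6-1 and in replicates 1 and 2, which stood at 22.4% of WT in replicate 3 (95% exact interval 15.9 to 31.5%, and 10.2 to 32.3% for single loci). Reads or RNA from WT cannot be told apart, because the outcome depends on the counting unit. On single counts, 12% of 50 loci low in replicates 1 and 2 (6 loci) lay below the level a WT share needs, which decides neither way. Among them was AT5G24240, at 56.8 counts against a lower limit of 110. If a fragment gives 2 counts, only 1 of the 50 did, which is under the 5% set beforehand for a WT share. The median of these 50 loci in replicate 3 was 14.4% of WT, close to the 14.7% of BRM. Seedlings of the mutant line with functional BRM and REF6 cannot be told apart either, because the gain of 5 loci low in brm-1, 14.2% of WT (10.2 to 18.9%) beside 13.2% for BRM, was 2.9% (-0.3 to 7.5%) without AT1G14250. No biological explanation was tested, as the labels give none for this library.

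No locus exceeded 6707 counts in any library, and the 10 highest took at most 0.46% of a library. One upper limit for every locus is argued against by the 100 highest mean counts, which spanned 2.46 times. Counting reads at one position only once may hold abundant genes down, and it would leave their spread below that of counting. From the sparsest to the densest 20% of loci the median variance over the Poisson variance was 2.13, 1.56, 1.19, 0.92 and 0.95, the last between the bounds set for the test and below the value near 2 that sampling gives if both mates were counted, but it was 1.97 in the densest 100. Differences between replicates also add to these values, and none of them decides. The 20 loci with the highest counts had a median of 6650 exon bases, against 1739 over all genes kept. A limit set by the number of positions may give this, but that was not tested, so the question stays open. No biological explanation was tested.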
